A study of Glycine max with 18 samples.

How the data were processed

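RNA was measured by RNA-seq in soybean (Glycine max, cultivar Williams 82), in nodules and in roots at 3 stages, 12, 22 and 36 days post inoculation (dpi), with 3 libraries per tissue and stage and 18 libraries in all. Per the labels, plants were inoculated with the nitrogen-fixing soil bacterium Bradyrhizobium diazoefficiens, the sampled plants were 15, 25 and 39 days old, and the root samples were mock treated. Nodules therefore came from inoculated plants and roots from plants that were not, so that a difference between nodule and root holds the difference in organ and the difference in treatment together. Libraries were made from isolated mRNA, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The labels do not say that the 3 libraries of a group came from separate plants or pools, so p-values measure only the spread between these samples, which may be technical.

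The deposited values are whole-number read counts per gene, not normalized, 1 list per library, with 56044 gene identifiers of the Wm82.a2.v1 annotation followed by 5 summary rows. Per the submitters' processing notes, the tools named are FastQC 0.11.4, Trimmomatic 0.35, TopHat2 2.0.13, HTSeq and DESeq2; the notes give neither the settings nor the strand option of the read counting. Whether the counting used strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. Reads with more than 1 alignment stand in a summary row of the deposited counts. Whether they were also counted in genes is not given in the sources used here. Soybean has many duplicated genes, and the count of a gene with a near-identical copy is therefore uncertain. The summary rows were kept out of library sizes and tests. Relative to the gene counts of a library, reads outside annotated genes came to 1.28% to 2.71%, ambiguous reads to 0.692% to 2.15%, and alignments that were not unique to 6.01% to 34.3%. The 34.3% was that of the second 36 dpi root library, and the next highest value was 17.5% in the first 12 dpi nodule library. The rows for low alignment quality and for unaligned reads were 0 in each library.

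The files do not pair the gene identifiers with names, and a table of 59048 RefSeq genes of another assembly (Glycine_max_v4.0) matched 0 of them. Gene names and functions are therefore not given. The 35 gene lists that had been fixed by description could not be formed, and the planned gene list tests were not run. Coordinates are not printed, because the annotation of the deposited identifiers was not used here. The first number in an identifier is the chromosome and the second gives the order along it, by the naming rule of this annotation; 55589 identifiers lie on 20 chromosomes and 455 are unplaced.

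Genes with low counts were removed with edgeR's filterByExpr by group, which left 39349 genes. Of the 56044 genes, 7212 had no count in any library. Library sizes were scaled by TMM, and 1 model with the 6 group means was fitted to all 18 libraries with 12 residual degrees of freedom (edgeR 4.0.16, estimateDisp, glmQLFit and glmQLFTest, R 4.3.3). Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over the genes tested, separately for each comparison. The comparisons were nodule against root at each stage, consecutive stages within each tissue, and the change of the nodule against root difference between consecutive stages (an interaction term). A count of the genes called at all 3 stages in one direction was made from the 3 nodule against root comparisons. A gene is called 8-fold changed where it passed the test with a log2 fold change of at least 3 either way. CPM values, the counts of a gene scaled to a common gene count total per library, were computed from the deposited counts; levels are given as mean ± SD over 3 libraries. The SE printed with a log2 fold change was derived from the test. It is the size of the log2 fold change fitted without shrinkage, divided by the square root of the F statistic. It is thus no estimate independent of the p-value, and the printed log2 fold changes are edgeR's shrunken ones. Principal components and correlations between libraries used log2 CPM with a prior count of 3.

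Genes named in the text followed a rule fixed before the data were examined. For nodule against root, these were the largest log2 fold changes each way among called genes with a mean of at least 50 CPM in the higher group and with the 3 libraries of one tissue above the 3 of the other; for stages and interactions the minimum was 20 CPM, and for interactions the separation of libraries was not required. Because identifiers carry no names, 2 genes each way were printed per comparison in place of 5. Where a group had 0 counts of a gene, the fold is a lower bound computed against 3 counts over the 3 libraries of that group. With 1 to 3 counts it is the mean CPM of the higher group divided by the pooled level of the lower group, which is its counts over the summed gene counts of its 3 libraries, with a 95% Poisson interval. The bounds use the same pooled total, and intervals and bounds cover counting error only.

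The comparison of nodule and root was tested on simulated data of 39349 genes. These were drawn from the mean of each gene over all 18 libraries, its spread and the real library sizes. In the nodules of the stage tested, 100 genes were changed 2-fold and 100 changed 4-fold, as many up as down. The changed genes were picked above a minimum mean level. Of 100 genes changed 2-fold, the test called 61 at 12 dpi, 63 at 22 dpi and 59 at 36 dpi; of 100 changed 4-fold it called 93, 95 and 94. False calls were 2 of 156 at 12 dpi, 7 of 165 at 22 dpi and 10 of 163 at 36 dpi. Apart from the changed genes, no gene differed between the simulated groups, while most genes differed in the real comparisons. These rates need not hold for the real data.

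Gene count totals per library ranged from 17167742 to 116766648. A count of 0 in a library allowed a level of up to 0.175 CPM in the smallest and 0.0257 CPM in the largest. Measures per library were compared between tissues with an exact two-sided permutation test over the 8000 relabelings within stages, whose smallest p is 0.00025; the 3 against 3 libraries of a single stage cannot give a p below 0.1. No pair of replicates agreed within sampling noise: the lowest chi-square per gene over 18 pairs was 4.55. Alternatives, fixed before the data were examined, were RLE size factors, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, fits on the compared groups alone, library sizes without the 20 most abundant genes, and leaving out each replicate in turn. Leaving out the first 12 dpi nodule library from comparisons that do not contain it, and leaving out single libraries for the printed genes and for the counts of genes seen in 1 tissue, were added after seeing the data.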

Results

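Nodules are organs that form on legume roots after contact with nitrogen-fixing bacteria. Gene expression was measured in soybean nodules and in mock-treated roots at 12, 22 and 36 dpi, with 3 libraries in each of the 6 groups, to follow how the nodule transcriptome differs from that of the root as the organ develops. Gene counts per library came to between 17167742 and 38103132 in 12 dpi roots, 18311627 and 116766648 in 22 dpi roots, and 17216729 and 34309774 in 36 dpi roots. In nodules they came to between 20945278 and 35447354 at 12 dpi, 42239342 and 73953318 at 22 dpi, and 30681246 and 49102552 at 36 dpi. Genes are given by identifier, since the files do not pair identifiers with names.

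Tissue separated the libraries along the first principal component, which held 73.2% of the variance. The roots lay between -202 and -162 on it. The nodules at 22 and 36 dpi lay between 212 and 224. The second component held 11.7% of the variance and ordered the stages within each tissue. The nodule libraries at 12 dpi did not lie together: the first lay at 39.4 on the first component and the other two both at 163. Pearson's r of log2 CPM across genes was 0.936 to 0.937 between this library and the other two, and 0.991 between the second and the third. Within the other 5 groups, r lay between 0.979 and 0.993. The first 12 dpi nodule library correlated with the roots at 0.827 to 0.866, and the other nodule libraries at 0.682 to 0.754.

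**Figure D1:**
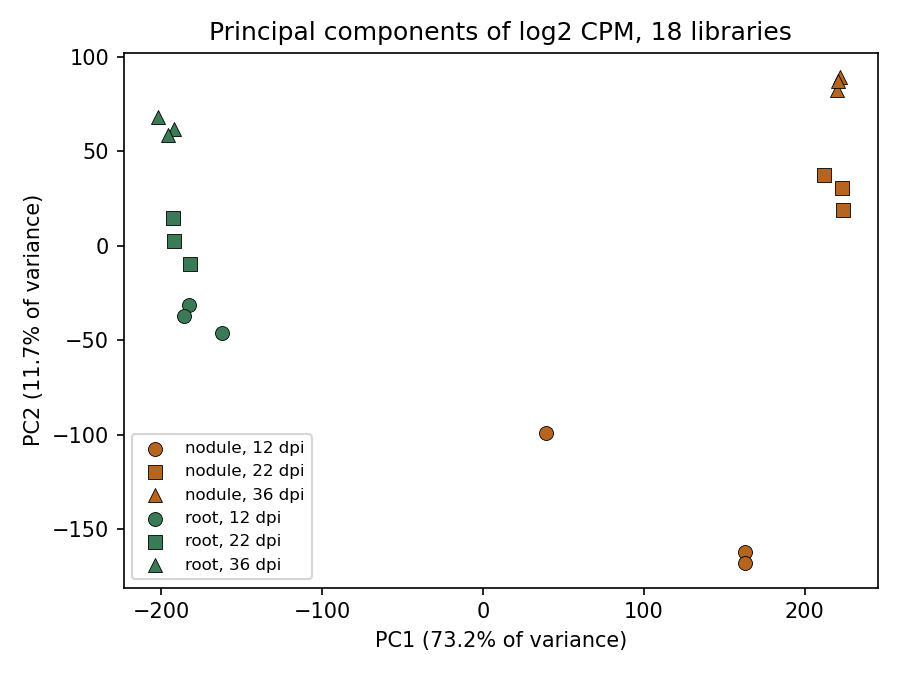
Each point is 1 library, placed by its first 2 principal components of log2 CPM, with colour for tissue and shape for stage. Roots lie between -202 and -162 on the first component and nodules at 22 and 36 dpi between 212 and 224, while 1 nodule library at 12 dpi lies at 39.4.

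Transcripts typical of roots were measured in each library through 188 genes that were at least 50-fold higher in roots than in nodules at both 22 and 36 dpi, with at least 5 CPM in 12 dpi roots. In the first 12 dpi nodule library these genes sat at a median of 0.311 of their mean level in 12 dpi roots, with quartiles of 0.172 and 0.61. In the other two 12 dpi nodule libraries the medians were 0.00774 and 0.00875, and in the 6 later nodule libraries they were between 0.00244 and 0.0126. A second set of 392 genes, at least 50-fold higher in nodules than in roots at 22 and 36 dpi, sat in that library at a median of 0.661 of their mean in the other two 12 dpi nodule libraries. Counts of called genes in comparisons that contain 12 dpi nodules were computed with and without this library.

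**Figure D2:**
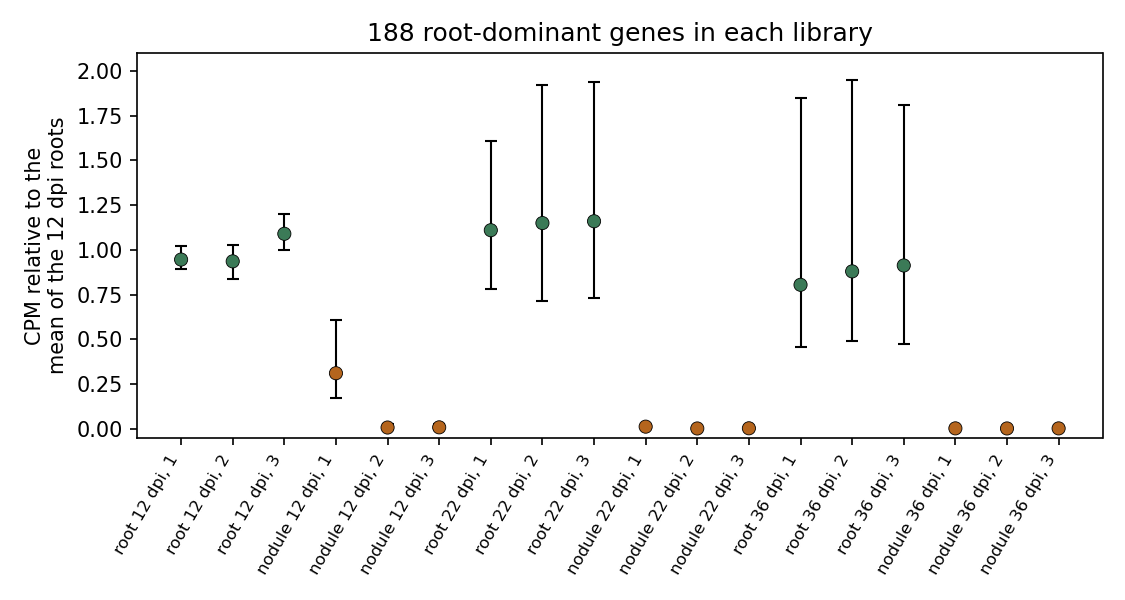
Each point is the median, over 188 root-dominant genes, of a library's CPM relative to the mean of the 12 dpi roots, and the bars span the quartiles over genes. The first 12 dpi nodule library stands at 0.311, and the other nodule libraries at 0.0126 or less.

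A few transcripts made up more of the nodule libraries than of the root libraries. The 20 most abundant genes held 6.61% ± 0.909 of the gene counts in 12 dpi nodules, 21.2% ± 0.685 at 22 dpi and 17.5% ± 1.39 at 36 dpi (mean ± SD, n = 3). In roots they held 4.01% ± 0.0517, 4.08% ± 0.0237 and 4.98% ± 0.113 (mean ± SD, n = 3). The difference over all stages was 10.7 percentage points, with p = 0.00025 in the exact permutation test within stages, the smallest p it can give, and 0.000583 after Benjamini-Hochberg adjustment over 7 measures. The most abundant gene alone held 4.71% ± 0.899 in 22 dpi nodules and 0.38% ± 0.0146 in 22 dpi roots. The number of genes that together held 50% of the counts was 1986 ± 30.9 in 12 dpi nodules and 1678 ± 81.5 in 12 dpi roots. At 22 dpi it was 885 ± 85.6 in nodules and 1608 ± 15.6 in roots, and at 36 dpi 1010 ± 124 and 1383 ± 65.9. Within each stage the nodule and root libraries did not overlap in this number. Nodules lay above roots at 12 dpi and below them at 22 and 36 dpi. Over the stages together the difference did not pass the test (exact permutation p = 0.0482, adjusted p = 0.0675). That test averages the signed differences of the stages, which partly cancel here, so it does not decide on differences within stages.

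**Figure D3:**
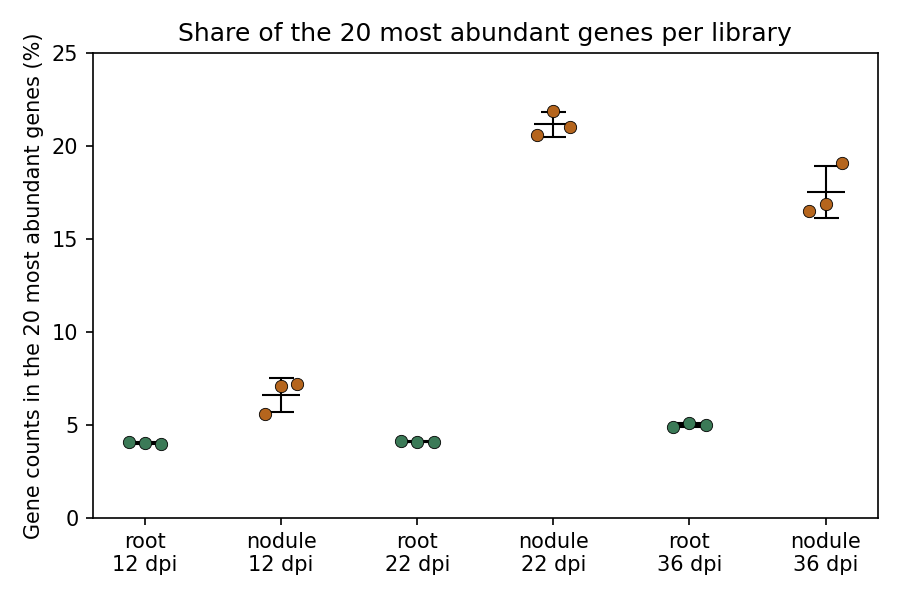
Each point is the percentage of a library's gene counts in its 20 most abundant genes, and the bars show the mean ± SD of 3 libraries. Nodules at 22 dpi stand at 20.6% to 21.9% and roots at 5.09% or less.

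At 12 dpi, nodules and roots were compared to find which transcripts set the young organ apart from the root. Glyma.07G113200 stood at 160 ± 41.7 CPM in nodules and had 2 counts in the 3 root libraries together, a ratio of 6872 to that pooled level with a counting interval of 1902 to 56744. Glyma.11G066400 stood at 120 ± 23 CPM in nodules and also had 2 counts in roots, a ratio of 5128 to the pooled level with an interval of 1419 to 42341. Both root counts of Glyma.11G066400 lay in the second 12 dpi root library, and without it the fitted log2 fold change went from 12.10 to 14.99, with no root count left; that of Glyma.07G113200 went from 12.49 to 11.72. Of the genes lower in nodules, Glyma.17G069500 fell from 115 ± 26.5 CPM in roots to 0.396 ± 0.487 CPM in nodules, with a log2 fold change of -8.44 (SE 0.528, edgeR adjusted p = 1.4e-09). Glyma.11G243200 stood at 95.7 ± 12.8 CPM in roots and 0.462 ± 0.799 CPM in nodules, with a log2 fold change of -8.02 (SE 0.74, edgeR adjusted p = 1.21e-07). All 29 nodule counts of Glyma.11G243200 lay in the first 12 dpi nodule library, and without that library the log2 fold changes of these last 2 genes were -14.80 for Glyma.11G243200, where no nodule count was left, and -10.16 for Glyma.17G069500. Without the second 12 dpi nodule library the value of Glyma.11G243200 was -7.39.

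In all, 26787 of 39349 genes differed between nodule and root at 12 dpi (edgeR quasi-likelihood test), 14967 higher in nodules and 11820 lower. At least 8-fold differences were seen for 2042 genes higher and 1907 lower in nodules. In the first nodule library root-dominant genes sat at a median of 0.311 of their level in 12 dpi roots. Without it 27653 genes differed, 13682 higher and 13971 lower, and 3999 genes were at least 8-fold lower. Of the 26787 calls, 25250 were kept in the same direction without that library, 1536 were lost and 1 turned.

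**Figure D4:**
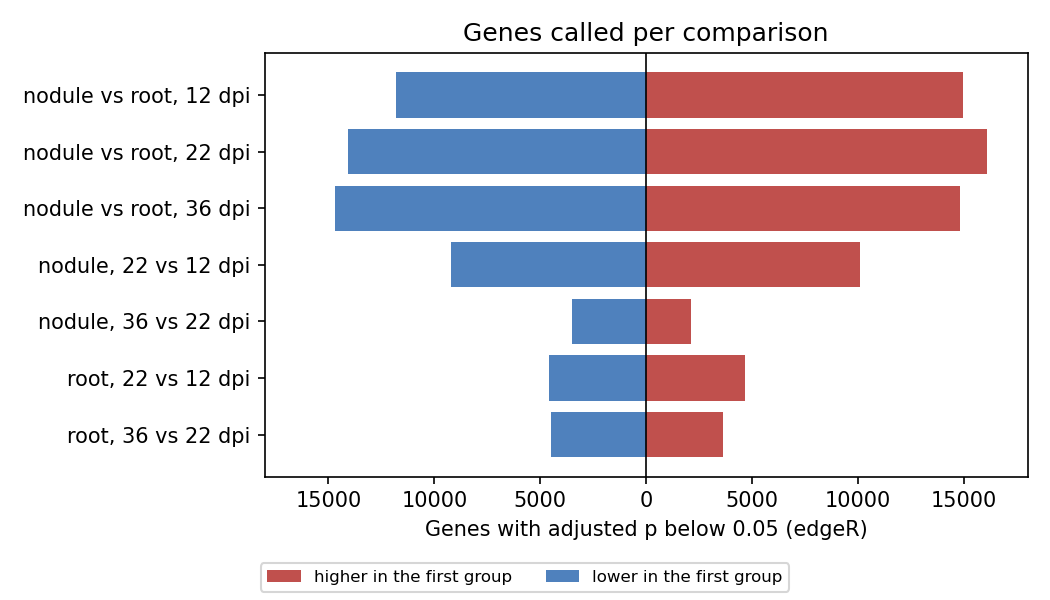
Bars give the number of genes called in each comparison by edgeR at an adjusted p below 0.05, to the right where they were higher in the first group named and to the left where they were lower. Nodule against root calls between 26787 and 30181 genes, and the steps between stages between 5583 and 19319.

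At 22 dpi, Glyma.U013100 stood at 82.2 ± 24 CPM in nodules with 0 counts in the 3 root libraries, at least 5155-fold higher. Glyma.08G071200 stood at 71.6 ± 13.5 CPM with 0 counts in roots, at least 4492-fold higher. Glyma.06G242900 fell from 180 ± 17.3 CPM in roots to 0.207 ± 0.243 CPM in nodules, with a log2 fold change of -9.16 (SE 1.81, edgeR adjusted p = 0.000231). Glyma.13G226000 fell from 61.2 ± 15.2 to 0.0811 ± 0.141 CPM, with a log2 fold change of -8.77 (SE 1.53, edgeR adjusted p = 0.000108). All 18 nodule counts of Glyma.13G226000 lay in the first 22 dpi nodule library, without which its log2 fold change was -14.10, and that of Glyma.06G242900 was -10.94. The first 12 dpi nodule library is not part of this comparison but enters the shared estimate of the spread. Glyma.06G242900 and Glyma.13G226000 stood there at 83.1 and 11.3 CPM, against 0.178 CPM or less in the other 12 dpi nodule libraries. Without it their edgeR adjusted p was 1.58e-12 and 1.38e-10, with log2 fold changes of -9.18 and -8.81. The test called 30181 genes, 16086 higher and 14095 lower in nodules, with 2761 at least 8-fold higher and 4095 at least 8-fold lower.

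At 36 dpi, Glyma.11G091600 stood at 468 ± 23.1 CPM in nodules and had 0 counts in the 3 root libraries, at least 12980-fold higher. Glyma.16G195200 stood at 287 ± 25.4 CPM with 0 counts in roots, at least 7966-fold higher. In nodules these 2 genes stood at 11.8 ± 1.87 and 32.7 ± 12.3 CPM at 12 dpi and at 449 ± 72.7 and 292 ± 23.2 CPM at 22 dpi. Glyma.14G148100 had 1 count in the 3 nodule libraries together and 59 ± 3.39 CPM in roots, a ratio of 7114 to the pooled nodule level with a counting interval of 1277 to 281001. Glyma.12G154300 likewise had 1 count in nodules and 57.5 ± 19.2 CPM in roots, a ratio of 6938 to the pooled level with an interval of 1245 to 274050. The single count lay in the first nodule library for Glyma.14G148100 and in the third for Glyma.12G154300. Without that library no nodule count was left and the fitted log2 fold changes went from -12.21 to -14.24 and from -12.17 to -14.25, and without the first nodule library that of Glyma.12G154300 was -11.54. The test called 29526 genes, 14813 higher and 14713 lower in nodules, with 2959 at least 8-fold higher and 4250 at least 8-fold lower.

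Across genes, the log2 fold changes of nodule against root correlated with Pearson's r = 0.94 between 22 and 36 dpi, 0.775 between 12 and 22 dpi, and 0.728 between 12 and 36 dpi; the stages share no libraries, and genes are not independent replicates. Without the first 12 dpi nodule library the values that involve 12 dpi were 0.804 and 0.768. The same direction at all 3 stages was called for 17597 genes, 44.7% of those tested. Of these, 9653 were higher in nodules, where independent lists would share 2303, and 7944 were lower, where independent lists would share 1583. At least 8-fold differences at all 3 stages were found for 1432 genes higher and 1105 lower in nodules. Without the first 12 dpi nodule library the shared calls came to 9006 higher and 9987 lower, and the genes at least 8-fold lower throughout to 2227. Opposite directions at different stages were called for 3242 genes.

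The shares of higher and lower calls depended on the scaling of the libraries. With RLE size factors the median log2 fold change of nodule against root over all genes moved by -0.16 at 12 dpi and at 22 dpi and by -0.081 at 36 dpi, and the share of calls higher in nodules was 48.3%, 47.9% and 47.5%, against 55.9%, 53.3% and 50.2% with TMM. The majority direction thus turned with the scaling, and for genes called at all 3 stages it did too, with 8193 higher and 9152 lower under RLE size factors. For each of the 10 counts of called genes, those of the stage steps and interactions included, the majority direction turned under at least 1 alternative or left-out library.

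From 12 to 22 dpi, nodules changed in 19319 genes, 10092 higher and 9227 lower at 22 dpi. Glyma.18G197800 rose from 1.1 ± 0.219 to 50.1 ± 7.71 CPM, with a log2 fold change of 6.04 (SE 0.278, edgeR adjusted p = 2.08e-10), and Glyma.06G120400 from 0.469 ± 0.131 to 20.5 ± 2.91 CPM, with a log2 fold change of 5.99 (SE 0.356, edgeR adjusted p = 2.12e-09). Glyma.01G130200 fell from 23.3 ± 4.47 to 0.0362 ± 0.0139 CPM, with a log2 fold change of -8.71 (SE 0.778, edgeR adjusted p = 4.36e-07), and Glyma.10G126100 from 102 ± 22.8 to 0.286 ± 0.1 CPM, with a log2 fold change of -7.99 (SE 1.28, edgeR adjusted p = 7.81e-05). Without the first 12 dpi nodule library 19860 genes were called, 11679 higher and 8181 lower, and of the 19319 calls 16945 were kept in the same direction, 2332 were lost and 42 turned. The majority turned with library sizes taken without the 20 most abundant genes (9257 higher, 9866 lower), with DESeq2 (9887 and 9916) and in a fit on these 6 libraries alone, which called 6352 higher and 6937 lower.

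From 22 to 36 dpi, nodules changed in 5583 genes, 2100 higher and 3483 lower. Glyma.05G007100 rose from 1.54 ± 0.287 to 56.1 ± 2.48 CPM, with a log2 fold change of 5.13 (SE 0.543, edgeR adjusted p = 2.4e-05), and Glyma.19G007700 from 1.73 ± 0.718 to 48 ± 7.01 CPM, with a log2 fold change of 4.72 (SE 0.45, edgeR adjusted p = 1.05e-05). Glyma.10G214500 fell from 640 ± 241 to 72.4 ± 13.8 CPM, with a log2 fold change of -3.19 (SE 0.294, edgeR adjusted p = 8.56e-06). Glyma.11G238500 fell from 95.1 ± 3.4 to 11.6 ± 4.74 CPM, with a log2 fold change of -3.08 (SE 0.714, edgeR adjusted p = 0.00849); without the second 36 dpi nodule library its adjusted p was 0.0542. Leaving out the first 12 dpi nodule library, which is not part of this comparison but enters the shared estimate of the spread and the scaling, gave 8375 genes. Without the third 22 dpi nodule library 3521 genes were called, without the first 36 dpi nodule library 3704, and without the second 3317. Calls higher at 36 dpi made up 37.6% with TMM and 46.2% with library sizes taken without the 20 most abundant genes, and a fit on these 6 libraries alone called 3177 genes higher and 2913 lower, which turns the majority direction.

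Roots changed in 9287 genes from 12 to 22 dpi, 4677 higher and 4610 lower. Glyma.20G192700 rose from 1.23 ± 0.546 to 47.1 ± 26.7 CPM, with a log2 fold change of 5.35 (SE 0.496, edgeR adjusted p = 2.23e-06), and Glyma.05G220500 from 3.8 ± 1.37 to 58 ± 19.6 CPM, with a log2 fold change of 4.06 (SE 0.345, edgeR adjusted p = 9.65e-07). Glyma.05G202700 fell from 47.4 ± 8.36 to 1.51 ± 0.559 CPM, with a log2 fold change of -4.94 (SE 0.286, edgeR adjusted p = 4.69e-08), and Glyma.10G166000 from 227 ± 44.3 to 12.5 ± 1.47 CPM, with a log2 fold change of -4.10 (SE 0.173, edgeR adjusted p = 1.01e-09). A fit on these 6 libraries alone called 14165 genes, and leaving out the second 22 dpi root library gave 6106.

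From 22 to 36 dpi, roots changed in 8123 genes, 3623 higher and 4500 lower. Glyma.05G128200 rose from 27.7 ± 2.35 to 100 ± 15.9 CPM, with a log2 fold change of 2.02 (SE 0.384, edgeR adjusted p = 0.00242), and Glyma.08G082400 from 10.1 ± 0.782 to 33.8 ± 6.84 CPM, with a log2 fold change of 1.90 (SE 0.193, edgeR adjusted p = 3.98e-05). Glyma.02G245600 fell from 22.8 ± 1.97 to 5.54 ± 2.23 CPM, with a log2 fold change of -1.89 (SE 0.243, edgeR adjusted p = 0.000168), and Glyma.04G227200 from 28.8 ± 2.26 to 7.02 ± 0.492 CPM, with a log2 fold change of -1.88 (SE 0.207, edgeR adjusted p = 6.52e-05). Calls higher at 36 dpi made up 44.6% with TMM and 28.2% with library sizes taken without the 20 most abundant genes, and a fit on these 6 libraries alone called 6122 genes higher and 5168 lower. With the first 12 dpi nodule library left out, which enters through the shared spread and the scaling, 6219 were higher and 5500 lower. The edgeR adjusted p of Glyma.05G128200 was then 1.09e-06. Without the first or the second 22 dpi root library 4414 and 5223 genes were called.

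Genes that changed in both tissues were counted for each step. From 12 to 22 dpi, 1252 genes were higher in both tissues and 1297 lower in both, where independent lists would share 1200 and 1081; 1465 were higher in nodules and lower in roots, and 1227 the reverse, where independent lists would share 1182 and 1097. Without the first 12 dpi nodule library, 2331 were higher in both and 1720 lower in both, where independent lists would share 1863 and 1294. Opposite directions were then called for 1936 higher in nodules and lower in roots and for 1140 the reverse, against 1847 and 1305 for independent lists. From 22 to 36 dpi, 392 genes were higher in both tissues, where independent lists would share 193, and 1313 were lower in both, where they would share 398. Opposite directions in this later step were called for 148 and 114 genes, against 240 and 321 for independent lists. Pearson's r of the log2 fold changes across genes between the tissues was 0.0068 for the earlier step, or 0.096 without that library, and 0.27 for the later one; genes are not independent replicates.

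The nodule against root difference itself changed from 12 to 22 dpi in 15780 genes, as tested by the interaction term, toward nodules in 7795 and toward roots in 7985. Leaving out the first 12 dpi nodule library gave a change toward nodules in 9394 and toward roots in 7045. Among 6112 of these that differed between nodule and root in the same direction at both stages, the difference grew in 4752 and shrank in 1360; without the first 12 dpi nodule library these numbers were 4499 and 3052. From 22 to 36 dpi the difference changed in 2351 genes, toward nodules in 1252 and toward roots in 1099, which is 53.3% toward nodules with TMM, 63.7% with RLE size factors and 74.6% with library sizes taken without the 20 most abundant genes. The majority lay toward roots without the first 12 dpi nodule library, with 2182 genes toward nodules and 2432 toward roots, and without the second 22 dpi nodule library, with 1259 and 1399. Of 1258 genes with the same direction at 22 and 36 dpi, the difference grew in 734 and shrank in 524.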

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

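The test of reads outside annotated genes was chosen after the data were seen; the interaction tests were planned. The interaction term, which tests whether the nodule against root difference changed between stages, called 15780 genes from 12 to 22 dpi and 2351 from 22 to 36 dpi (edgeR). With the tissue labels shuffled within stages, 100 labelings in all with the real one, 1 gave as many genes as the real labels for the earlier step, the real one itself, and the highest other count was 8582. For the later step 4 of 100 did, the real one included, and the highest other count was 21944. For these interactions the shuffles do not decide whether chance can be excluded. Shuffles that mixed the tissues at both stages of a step, which turns the difference between tissues into spread, gave 0 genes for either step. The 3 shuffles with larger counts for the later step all left the libraries of 1 of its stages grouped by tissue, so that their counts point to the difference between tissues. For genes called in one direction at all 3 stages, 1 of 100 labelings gave as many as the 17597 found, the real one. The highest other count was 0. Each of the other labelings mixed the tissues at some stage, which again turns their difference into spread. The shuffles thus argue only against the case of no difference between tissues at all. They do not show how many of the 17597 calls are due to chance. The labels also do not say that the libraries are separate samples.

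From 12 to 22 dpi the difference of Glyma.13G243500 moved toward nodules by 8.37 on the log2 scale (edgeR adjusted p = 1.92e-07): it stood at 1.6 ± 0.2 and then 37.4 ± 4.99 CPM in nodules, and at 0.28 ± 0.216 and then 0.033 ± 0.019 CPM in roots. Without the second 12 dpi root library the value was 7.48. Glyma.07G192900 moved by a fitted 8.35 (edgeR adjusted p = 0.000873), from 0.965 ± 0.135 to 29.5 ± 3.34 CPM in nodules; it had 0 counts in 22 dpi roots, so this value depends on the fit and is no bound. The difference of Glyma.11G225000 moved by -16.42 (edgeR adjusted p = 0.000379) and that of Glyma.09G150400 by -10.60 (edgeR adjusted p = 8.47e-05). Both rest in part on the first 22 dpi root library, where they stood at 24.1 and 40.5 CPM against 1.3 CPM or less in the other two; without it the values were -9.18 for Glyma.11G225000 and -7.09 for Glyma.09G150400. Without the second or the third 22 dpi root library they were -17.04 and -17.03 for Glyma.11G225000 and -11.18 in both fits for Glyma.09G150400. Without the second or the third 12 dpi root library that of Glyma.11G225000 was -15.71 and -18.56.

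From 22 to 36 dpi the difference of Glyma.05G007100 moved toward nodules by 9.55 (edgeR adjusted p = 0.000461) and that of Glyma.19G007700 by 6.79 (edgeR adjusted p = 0.000728). Both stood under 3 CPM in each root library of these stages; without the first 22 dpi root library the values were 8.13 for Glyma.05G007100 and 5.91 for Glyma.19G007700, and without the third 36 dpi root library they were 12.73 and 6.06. That of Glyma.05G007100 was 10.34 without the third 22 dpi root library and 8.90 without the first 36 dpi root library, and that of Glyma.19G007700 was 8.22 without the second 36 dpi root library. The difference of Glyma.07G139400 moved by -4.25 (edgeR adjusted p = 0.0134), with 1.65 ± 0.167 and then 0.0611 ± 0.0366 CPM in nodules; without the second 36 dpi nodule library its adjusted p was 0.0514. That of Glyma.09G282700 moved by a fitted -4.19 (edgeR adjusted p = 0.0404), although it rose in nodules from 25.1 ± 1.79 to 40.8 ± 3.14 CPM; it had 0 counts in 22 dpi roots and 0.0889 ± 0.0266 CPM in 36 dpi roots, so that both roots lay near the floor, and leaving out single libraries ended this call in most fits, with adjusted p of 0.0148 to 0.146. With library sizes taken without the 20 most abundant genes the adjusted p was 0.0538.

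Reads outside annotated genes, which no comparison of the report used, came to 2.12% ± 0.278 of the gene counts in nodules and 1.41% ± 0.119 in roots (n = 9 each, exact permutation p = 0.00025, the smallest it can give; adjusted p = 0.000583 over 7 measures). Each nodule library lay above each root library, at 1.78% to 2.71% against 1.28% to 1.64%.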

How the results depend on the processing

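Leaving out the first 12 dpi nodule library from comparisons that do not contain it, and leaving out single libraries for the printed genes and for the counts of genes seen in 1 tissue, were chosen after seeing the data; the other alternatives were planned. Under RLE size factors, no filter, DESeq2, the replicate block and library sizes without the 20 most abundant genes, each of the 10 counts stayed within 1.5 times its value. Fits on the compared groups alone gave 14165 genes for roots from 12 to 22 dpi in place of 9287, and 3793 for the interaction from 22 to 36 dpi in place of 2351. Leaving out single libraries of the groups compared gave 23622 to 27653 genes for nodule against root at 12 dpi, 28545 to 29705 at 22 dpi, 27900 to 28694 at 36 dpi, and 15836 to 18993 called at all 3 stages. For nodules it gave 16482 to 19860 from 12 to 22 dpi and 3317 to 5144 from 22 to 36 dpi, and for roots 6106 to 8321 and 4414 to 6278. For the interaction it gave 13705 to 16439 from 12 to 22 dpi and 1320 to 2658 from 22 to 36 dpi, with 1456 without the first 22 dpi root library, 1524 and 1320 without the first and the third 22 dpi nodule library, and 1436 and 1445 without the second and the third 36 dpi nodule library. The cause of these moves was not tested. Without the first 12 dpi nodule library, counts that do not contain it rose to 8375 for nodules and 11719 for roots from 22 to 36 dpi, 12499 for roots from 12 to 22 dpi and 4614 for the interaction from 22 to 36 dpi, where it enters through the shared estimate of the spread and the scaling. Over these settings and left-out libraries, higher calls made up 48.3% to 56% at 12 dpi, 47.9% to 53.6% at 22 dpi and 47.2% to 51.3% at 36 dpi for nodule against root, and 47.2% to 55.4% of genes called at all 3 stages. From 12 to 22 dpi they made up 47.8% to 58.8% in nodules, 47.8% to 52.1% in roots and 45.4% to 57.1% in the interaction, and from 22 to 36 dpi 34% to 52.2%, 28.2% to 54.2% and 47.3% to 74.6%.

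The replicate numbers did not pair the samples: over 45 pairs with the same number the correlation of deviations from the group means had a median of -0.059 and ranged from -0.22 to 0.35, against a median of 0.011 for different numbers, and 5 of 18 libraries matched best a library of their own number. With the replicate number as a block the counts were 26474, 29905 and 29189 for nodule against root at 12, 22 and 36 dpi, and 1902 for the interaction from 22 to 36 dpi. For the 36 log2 fold changes printed by the rule for named genes, 212 values under settings other than leaving out a library kept direction and call and 2 lost the call, and with single libraries left out 275 kept both and 13 lost the call; none turned. All but 2 of the lost calls were those of Glyma.09G282700, whose adjusted p was 0.0573 under the block and 0.0538 with library sizes without the 20 most abundant genes. DESeq2 gave no adjusted p for Glyma.14G148100 and Glyma.10G126100, and these entered no count. The gene list tests and their 4 alternatives were not run, since no list could be formed.

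The 3 against 3 libraries of a comparison allow 10 splits, too few for a share under 0.05, and in each comparison 1 of the 10, the real one, gave as many genes. Against the real 26787, 30181 and 29526 genes for nodule against root at 12, 22 and 36 dpi the highest other count was 0. Against 19319 and 5583 for the nodule steps it was 21 and 0, and against 9287 and 8123 for the root steps it was 7 and 1. Each other split mixed the libraries of the compared groups, which turns their difference into spread. The low counts thus largely follow from the splits and do not show how many calls are due to chance. Depth limits the lowest genes: a count of 0 allowed 0.175 CPM in the smallest library.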

Other observations

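The test against the spread around the 12 dpi roots, the extra gene selections for the mixed library, the counts of genes seen in 1 tissue, the values for the first 22 dpi root library and the chromosome shares were chosen after the data were seen. Genes with 0 counts in the 3 libraries of one tissue and a mean of at least 1 CPM in the other numbered 105 at 12 dpi, 116 at 22 dpi and 232 at 36 dpi for nodules, and 22, 40 and 130 for roots. Of the nodule genes, 14, 23 and 59 reached 10 CPM; of the root genes 0, 0 and 13 did. Single libraries set several of these counts. Without the first nodule library the root genes numbered 226 at 12 dpi, 201 at 22 dpi and 229 at 36 dpi, with 31, 24 and 20 at 10 CPM. Without the second 12 dpi root library the nodule genes of that stage numbered 250, with 56 at 10 CPM, and without the third 36 dpi root library 102 nodule genes reached 10 CPM. Leaving out any other library of the groups moved none of these counts by over 1.5 times. The counts of 0 allowed at most 0.036 CPM in the pooled libraries of a group, and depth differs between groups.

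Genes of large tissue difference lay beside each other in the order of their identifiers. Of 2738 placed genes at least 8-fold higher in 22 dpi nodules, 25.2% had a tested neighbour that was too, in 382 neighbouring pairs, against a mean of 144 and a highest value of 177 in 1000 shuffles within chromosomes. Of 4072 genes at least 8-fold lower, 23.1% did, in 519 pairs against a mean of 318 and a highest of 376. The hypothesis that neighbouring genes respond together predicted a ratio above 1.2 to the shuffled mean, and the ratios were 2.65 and 1.63; tandem copies that share reads or sequence may give the same result and were not separated. On chromosome 3, 13.4% of 1836 tested genes were at least 8-fold lower in nodules against 10.3% elsewhere (Fisher's exact test, adjusted p = 0.00129 over 40 tests); the other 39 tests had adjusted p of 0.131 or more, and since neighbouring genes are not independent these p-values are too small.

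The first 12 dpi nodule library lay between the other nodules and the roots. Against lower depth, the other 12 dpi nodule libraries thinned to its total held root-dominant genes at 0.0082 of 12 dpi root level, against 0.311 here. Thinning leaves the mean CPM of a gene unchanged, so this share could hardly have come out otherwise. Younger nodules predicted that genes equal in 12 dpi roots and nodules would lie further from the 22 dpi level. They were displaced by -0.31 on the log2 scale (95% interval over genes -0.35 to -0.27), that is, toward it. Of these 490 genes, 460 were lower at 22 dpi, and root RNA of another stage could displace them too. The displacement thus does not decide on younger nodules where such RNA is present. Root RNA in this library is a candidate explanation: nodule-dominant genes sat at 0.661 of their level in the other two, near the 0.689 left by a root share of 0.311, although of 4 gene selections, the one made by the level in 36 dpi roots gave a share of 0.61 and so 0.39 left. Against the level in 36 dpi roots that selection gave a share of 0.328 and 0.672 left, and the 4 selections left 0.644 to 0.672. The RNA of the sampled 12 dpi mock roots is argued against by the spread of log2 ratios across the 188 genes. Its SD was 1.46 against them and 0.353 against the 36 dpi roots. The nearness of 0.661 to 0.689 thus rests on roots that are argued against as the source. Against the level in 36 dpi roots the 188 genes gave a median share of 0.35, with 0.65 left. Reads of the second 36 dpi root library predicted that the deviations of this nodule library would correlate best with that root library. The correlation was 0.13 with the second, -0.37 with the first and 0.39 with the third, a lead of -0.25. Over the 4 selections the lead was -0.37 to -0.026. The selection made by the level in 36 dpi roots came near a tie, at 0.29 for the second and 0.32 for the third. No selection put the second library ahead, which argues against its reads, although deviations of libraries from their common mean are not independent. Root tissue of inoculated plants taken with the nodules, or RNA of another root sample, stays open; no biological explanation other than younger nodules was tested, because the labels give none within a group.

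The second 12 dpi root library and the first 22 dpi root library held more nodule-dominant transcripts than the other roots, at medians of 0.00797 and 0.00719 of the 12 dpi nodule level over 392 genes against 0.00191 or less. Whole nodule RNA in the second 12 dpi root library, as a candidate explanation, predicted 1 common share for all these genes. The 20 most abundant sat there at 0.23% and the rest at 0.82%, a 3.54-fold gap that argues against a single share of 12 dpi nodule RNA. In the first 22 dpi root library these values were 0.53% and 0.73%. The genes were chosen as low in 22 dpi roots, and the shares were taken against 12 dpi nodules. These values thus do not decide on a single share of nodule RNA there. The rest stood above the 20 most abundant in each other root library too. In the first 12 dpi root library they stood at 0.11% against 0.033%, and in the first 36 dpi root library at 0.078% against 0.021%. A gap in this direction is thus not particular to the second 12 dpi root library. RNA of another stage stays open for the second 12 dpi root library, and no biological explanation was tested. In the second 36 dpi root library 11 of the 20 most abundant had 0 counts.

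From 22 to 36 dpi, 1705 genes changed in the same direction in nodules and roots, against 592 for independent lists, while 262 went opposite ways against 561. Traces of root RNA in nodules are argued against by the shared genes' median nodule to root ratio of 0.68 at 22 dpi. A single library is argued against by the lowest ratio of shared to expected genes over 12 leave-one-out fits, 2.63. Without the first 12 dpi nodule library, which is not part of this step, the ratio was 2.4. With RLE size factors it was 2.85, but these shifted log2 fold changes by a median of only 0.027 in nodules and -0.049 in roots. Library sizes without the 20 most abundant genes shifted them by 0.04 and -0.11, and the ratio was not computed with that setting. Scaling is thus argued against only as far as RLE size factors reach. From 12 to 22 dpi the ratio was 1.12, or 1.28 without the first 12 dpi nodule library. Plant age, common to both tissues of a stage, may underlie the shared change, and so may growth or handling on the days of sampling, for which the labels give no batch; neither was tested.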
